A study of Mus musculus with 12 samples.

How the data were processed

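RNA was isolated with the mirVana kit and miRNAs were measured by quantitative PCR assays, per the labels' protocols and the series text, which gives 6 mice as biological replicates. The deposited main table holds raw threshold cycles (Ct), per the file headers: 1 Ct is 1 PCR cycle, a lower Ct means more RNA, and a well that did not amplify is listed at 40. The instrument, threshold and baseline settings are not given in the sources used here. The main table has 517 miRNA assays, of which 4 (miR-100, miR-10a, miR-146b and miR-99a) are blank, and 11 rows of 6 control RNAs (U6, U87, Y1, snoRNA135, snoRNA202 and snoRNA429), whose repeated rows were averaged. A second deposited table holds raw Ct values of these 4 assays and of 4 control RNAs from a separate run, whose method is not given in the sources used here. The third deposited table holds processed values of 519 assays. Compared with the raw table over 513 rows, it equals Ct minus the mean of U6 and snoRNA429 of the same sample to within 5e-05 cycles, and for the 4 separately run assays Ct minus snoRNA429 of that run, so a lower value means more RNA. Its column medians lay between 10.7 and 13.8 cycles. How many cards a sample took, and which assay was on which card, could not be read from the tables, so no scaling per card was made.

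Samples were grouped by the labels into 6 control right and 6 ligated left carotid arteries, with replicate numbers 1 to 6 in each group. The labels do not say that same-numbered samples came from the same mouse. Deviations of same-numbered samples from their group means correlated across assays with r between 0.283 and 0.622. The main fit did not pair the samples. The numbers were used as pairs only in comparisons and tests that say so. The control sample correlated best with its own number in 1 of 6 cases, and with the 2 sets of numbers 1 to 3 and 4 to 6 removed, r lay between -0.26 and 0.226 and was above 0 in 4 of 6. The sets were found in the data and also stand as 2 blocks of columns in the raw table. Principal component 1 (34.9% of variance) separated these sets and component 2 (18.1%) the groups. Over the assays detected in all samples, the closest of the 66 pairs of samples, ligated 5 and 6, differed by 0.332 cycles on average, and the closest pair of different groups by 0.834, while the repeated rows of a control RNA in a sample differed by 0.642 on average. No pair had equal Ct values in more than 1 assay. These values do not show whether the closest samples were measured from separate arteries, and all 12 were kept as separate samples because the series text gives 6 mice.

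The following choices were made before the data were examined. A miRNA was called detected at a Ct below 35, undetected wells were set to 35, and each sample was scaled to the mean Ct of the miRNAs detected in all 12 samples. Assays detected in at least 4 of 6 samples of at least 1 group were tested. Minus the scaled Ct, a log2 level, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment, and adjusted p-values below 0.05 were called. Where only the group with the lower level had undetected wells, a difference was read as a lower bound on the change. This holds only if an undetected well held little RNA and was not a failed reaction, which was not tested. miR-433 puts it in doubt, with 3 control samples at a Ct of 21.97 to 25.04 and 3 at 40. Where the group with the higher level also had undetected wells, as for miR-501-3p, miR-219 and miR-10b*, the fitted difference is no bound. PCR efficiency was taken as a doubling per cycle. The 18 miRNA lists, for leukocytes, inflammation, contractile and growing smooth muscle, endothelium, shear response, red blood cells, striated muscle, neurons, epithelium, liver and kidney, mesenchyme and fibroblasts, and 6 miRNA families and clusters, were tested with camera at a preset correlation of 0.01 and with fry. Members were matched by miRNA name and arm, and lists share members. miR-122 was not tested and miR-712 had no matching assay. The rule for named miRNAs took the 10 largest changes in each direction among called miRNAs detected in all 6 samples of the higher group, a fixed set of 26 miRNAs known in vessels, immune cells or other tissues, up to 4 members of each list with the lowest p, the control RNAs, and any with an outlying sample. miRNAs outside the rule that the text names were chosen after their values were seen: miR-34a, miR-31, miR-132, miR-511, miR-501-3p, the miR-30 miRNAs, miR-411*, miR-21*, miR-10b*, miR-193, miR-26b and let-7a.

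Per-sample measures were compared by exact two-sided permutation tests over all 924 splits and detection by Fisher's exact test. The separate run was tested in the same way, scaled to its own control RNAs. Outlying samples were found with Dixon's ratio above 0.625 in a group of 6. Alternatives covered the reference for scaling, the detection limit, the filter, the treatment of undetected wells, the replicate block, array weights, the variance model, and leaving out each sample. The set block, each set alone, the reference U6 and snoRNA429, the exact permutation of list means, permutation within sets, and the paired sign-flip tests of the list means, the control RNAs and the separate run were added after seeing the data. A list of 10 fat-associated miRNAs was also written after the data were seen. The number of arrays limits the precision. The procedure was tested on simulated data with the means and SDs of the 339 assays. There were 10 simulated sets with 80 changed assays each, and the mesenchymal and fibroblast list was also shifted by 1.5. Of changes of 1 log2 unit 37.7% were called, of changes of 2 72.3%, and 5.97% of calls were in unchanged assays. Values were drawn independently, without the split of replicate numbers, pairs or correlation between assays, so these rates may not hold for the real samples.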

Results

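Levels of miRNAs were measured by quantitative PCR assays in carotid arteries of female apoE-deficient mice, a strain that develops atherosclerosis on a fatty diet. The left carotid artery had been partially ligated, which lowers and disturbs its blood flow, and the right carotid artery was left untreated. The mice were 6 to 8 weeks old and received a high-fat diet with 21% fat and 0.15% cholesterol for 6 weeks. There were 6 ligated left arteries and 6 untreated right arteries from 6 mice, 12 samples in all, with 1 sample per array by the series text. By these counts each mouse would have given both arteries, but which ones belong together is not given. The main tests treated the 12 arteries as independent. The comparison asks which miRNAs differ between the ligated and the untreated artery. Of 513 miRNA assays with values in the main run, 283 were detected in all 12 samples, 113 in none, and 339 were detected often enough to be tested. Between 317 and 341 assays were detected per control sample and between 330 and 357 per ligated sample. Levels are given as log2 values relative to the mean of the miRNAs detected in every sample, so a difference of 1 stands for a doubling if each cycle doubles the product.

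The ligated arteries held more of several miRNAs of blood-borne immune cells and of inflammation, and less of miR-143, miR-145 and miR-1, which were 3 of the 5 tested miRNAs of contractile smooth muscle. In limma's moderated test with Benjamini-Hochberg adjustment, 25 miRNAs were higher and 17 lower in ligated arteries, and 297 of the 339 did not pass. Leaving out 1 sample gave 15 to 26 higher and 9 to 20 lower, with 16 and 9 without control 4, 15 and 11 without control 6, 10 lower without control 3, and 11 lower without control 1, ligated 5 or ligated 6. Raw Ct gave 57 higher and 0 lower, with the median over all assays moved to 0.93, while array weights gave 51 and 50, an unequal-variance test gave 13 higher, and 37 and 30 were called with numbers 1 to 3 against 4 to 6 as a block. The level changed 2-fold or more for 22 of the higher and 13 of the lower miRNAs. miR-155, a miRNA induced in activated macrophages and lymphocytes, had a level of -0.11 ± 0.77 (SD, n = 6) in control arteries and 2.33 ± 0.51 (SD, n = 6) in ligated arteries. Its log2 fold change was 2.44 ± 0.38 (SE), or 5.44-fold, with an adjusted p of 0.00494, and the ligated sample was higher in 6 of 6 same-numbered comparisons. miR-145, a miRNA of contractile smooth muscle, went from 11.51 ± 1.02 (SD, n = 6) to 9.12 ± 0.49 (SD, n = 6), and fell by 2.39 ± 0.45 (SE) on the log2 scale, with an adjusted p of 0.00669, lower in 5 of 6 same-numbered comparisons. Of the 42 called miRNAs, 37 moved in the called direction in all 6 same-numbered comparisons. Of these calls, 23 held whichever 1 sample was left out, and 19 were lost without at least 1 sample (limma, adjusted p up to 0.102). The samples numbered 1 to 3 and those numbered 4 to 6 stood apart on the first principal component. Over the same 339 assays, limma called 5 higher and 0 lower within numbers 1 to 3, where 39 had an unadjusted p under 0.05, and 50 higher and 51 lower within numbers 4 to 6. The median SD within a group was 0.592 in numbers 1 to 3 and 0.285 in numbers 4 to 6. Whether the closest samples, ligated 5 and 6, came from separate arteries is not shown. Adjusted p-values within numbers 4 to 6 may therefore be too small, here and below. All 42 called miRNAs had the same sign in both sets, and for 20 of them the values within the sets were over 1.5 times apart, 15 of them larger in numbers 4 to 6. A test of the difference between the sets called 0 of the 42, with a lowest adjusted p of 0.0637 for miR-187. The log2 fold changes within numbers 1 to 3 and 4 to 6 were 3.11 and 1.78 for miR-155 and -1.49 and -3.29 for miR-145. Tested on the deposited value table, the counts were 8 higher and 4 lower, and with these data rescaled to U6 and snoRNA429 they were 7 higher and 3 lower.

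**Figure D1:**
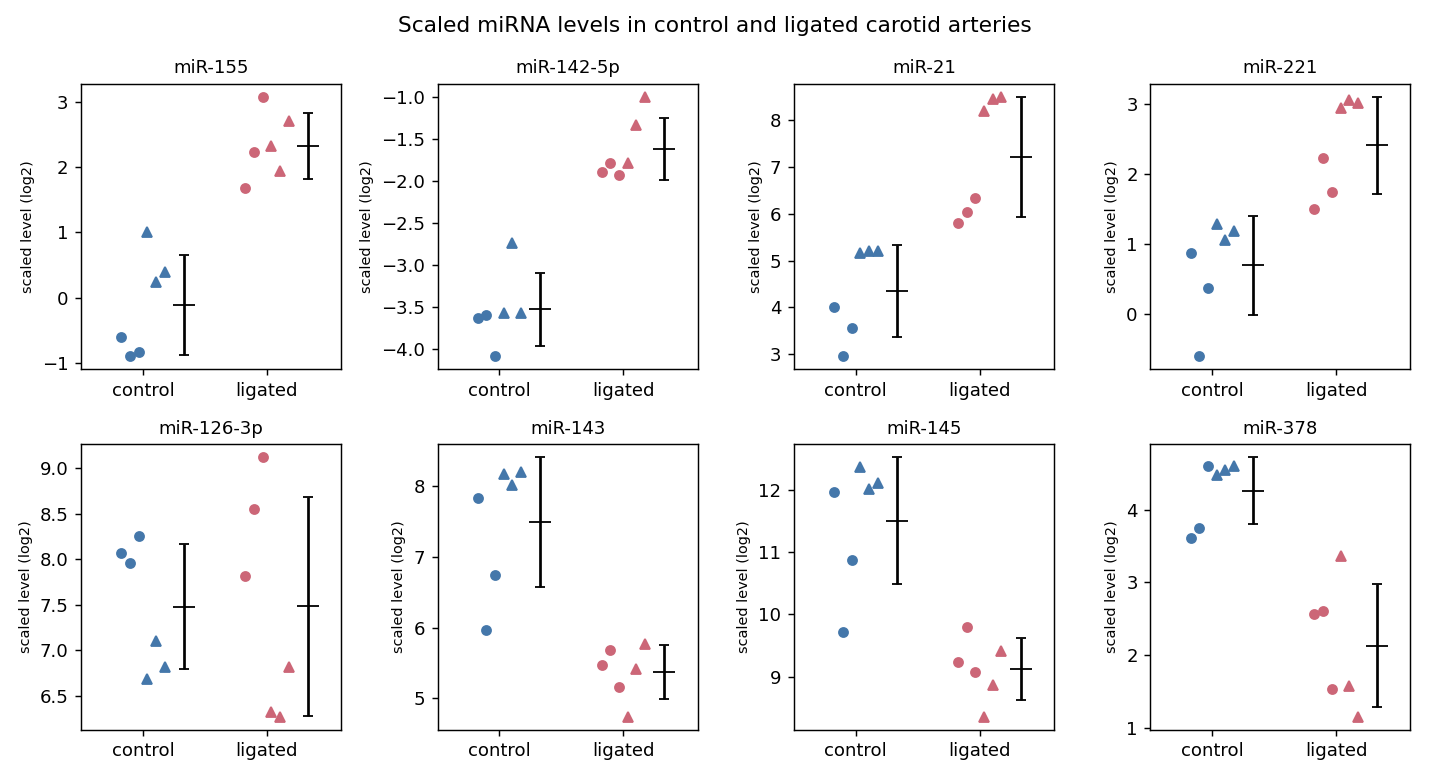
Scaled levels (log2, relative to the mean of the miRNAs detected in every sample) of 8 miRNAs in 6 control and 6 ligated carotid arteries. Circles are samples numbered 1 to 3, triangles samples numbered 4 to 6, and the black bars give the mean and SD of each group. miR-155, miR-142-5p, miR-21 and miR-221 sat higher in ligated arteries and miR-143, miR-145 and miR-378 lower, while miR-126-3p had a log2 fold change of 0.00 ± 0.54 (SE).

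Leukocyte-enriched miRNAs were higher in ligated arteries. Of the 7 members tested, 5 rose and none fell, and 6 rose when adjusted over the list alone. miR-142-5p and miR-142-3p, the arms of a hairpin expressed in blood cells, rose by 1.92 ± 0.26 (SE) and 1.77 ± 0.50 (SE). miR-342-3p rose by 1.99 ± 0.58 (SE), and its other arm miR-342-5p by 3.62 ± 0.86 (SE), detected in 4 of 6 control and 6 of 6 ligated samples. The call of miR-342-3p held in 18 of 35 alternatives and was lost when any 1 sample other than control 2 or ligated 5 was left out (limma, adjusted p up to 0.102). That of miR-142-3p held in 20 of 35 and was lost without control 1, 2, 3, 4 or 6 or ligated 4, 5 or 6 (adjusted p up to 0.0886). miR-223, abundant in neutrophils and monocytes, had a log2 fold change of 1.67 ± 0.57 (SE) and an adjusted p of 0.0905, which became 0.00768 with the replicate number as a block. miR-150, abundant in mature lymphocytes, had a log2 fold change of 0.46 ± 0.32 (SE) and an adjusted p of 0.461, and had opposite signs in the sets, with 1.04 within numbers 1 to 3 and -0.11 within numbers 4 to 6. The median of the list was 1.92, and limma's camera gave an adjusted p of 1.2e-05, or an adjusted p of 0.00715 with an estimated correlation. With the preset correlation, 36 of 100 splits of the samples, the real one among them, gave as many called lists. A camera call alone is therefore weak evidence for this and the following lists. An exact permutation test of the list mean gave p = 0.00216, the smallest that 924 splits allow, and an adjusted p of 0.0130. With paired numbers, an exact sign-flip test of the list means gave 6 lists p = 0.0312, the smallest that 6 pairs allow, and none passed after adjustment over the 18 lists (adjusted p 0.0938). They were this list, the next 3 described, the endothelial-enriched list and the striated muscle list. The medians were 1.91 within numbers 1 to 3 and 1.78 within numbers 4 to 6.

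Inflammation-induced miRNAs were higher as a list, with 4 of 7 tested members higher, 1 lower and 2 not past the threshold. Adjusted over the list alone, 6 rose and 1 fell. miR-21, widely induced in injured and inflamed tissue, rose by 2.86 ± 0.62 (SE), or 7.24-fold, and miR-146a, a brake on innate immune signalling, by 1.65 ± 0.40 (SE), with 2.09 and 1.21 within the sets. miR-147 rose by 4.10 ± 0.66 (SE) and was detected in 1 of 6 control and 6 of 6 ligated samples, so its size depends on the value given to undetected wells. With those left missing, which leaves 1 control sample, the log2 difference was 2.22. miR-187 fell by 2.50 ± 0.74 (SE), with log2 fold changes of -1.16 within numbers 1 to 3 (limma, adjusted p 0.389) and -3.84 within numbers 4 to 6 (adjusted p 0.00105). Its call held in 19 of 35 alternatives and was lost without any 1 control sample or ligated 4, 5 or 6 (adjusted p up to 0.0990), and that of miR-146a was lost without control 4 (adjusted p 0.0507). miR-132 and miR-511 had log2 fold changes of 0.65 ± 0.28 (SE) and 1.34 ± 0.59 (SE) and adjusted p-values of 0.210 and 0.230, which became 0.0321 and 0.0288 with the replicate number as a block. The list had a median of 1.65, a camera adjusted p of 0.00108, an adjusted p of 0.0303 with an estimated correlation, and an exact permutation p of 0.00216 (adjusted 0.0130). The medians were 2.09 within numbers 1 to 3 and 1.21 within numbers 4 to 6. miR-146b was blank in the main run and was measured in a separate run, where, scaled to the 4 control RNAs of that run, it was higher in ligated arteries by 2.82 on the log2 scale, or 7.05-fold (exact permutation p = 0.00216, two-sided, n = 6; adjusted 0.00288). The difference was 2.27 within numbers 1 to 3 and 3.36 within numbers 4 to 6. Its other arm, miR-146b*, rose by 5.37 ± 0.92 (SE) in the main run and was detected in 2 of 6 control and 6 of 6 ligated samples. The size of this rise also depends on the value given to undetected wells. Its call held in 32 of 33 alternatives, over which the log2 fold change ran from 2.67 to 8.71.

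Of the 5 tested miRNAs of the contractile smooth muscle list, 3 fell in ligated arteries, none rose and 2 did not pass the threshold. Camera gave the list an adjusted p of 0.00108, lost with an estimated correlation (adjusted p = 0.166). Adjusted over the list alone, 3 fell. miR-143, transcribed next to miR-145 and enriched in smooth muscle, fell by 2.12 ± 0.40 (SE) and was lower in the ligated sample in 6 of 6 same-numbered comparisons, with -1.41 and -2.82 within the sets. miR-1, a miRNA of heart and skeletal muscle as well as smooth muscle, fell by 1.75 ± 0.45 (SE), a call lost without control 1, 3, 4 or 5 or ligated 2 or 4 (limma, adjusted p up to 0.0571). miR-1, miR-133a and miR-133b are also 3 of the 4 tested members of the striated muscle list, whose median was -1.25. miR-133a had a log2 fold change of -1.23 ± 0.86 (SE) and an adjusted p of 0.461, with -0.47 within numbers 1 to 3 (adjusted p 0.824) and -1.99 within numbers 4 to 6 (adjusted p 0.00406). miR-133b had a log2 fold change of -1.28 ± 0.63 (SE), with an adjusted p of 0.268 that became 0.0321 with the replicate number as a block, and -0.70 (adjusted p 0.735) and -1.86 (adjusted p 0.00820) within the sets. The test of the difference between the sets gave adjusted p-values of 0.603 and 0.747. The list median was -1.75, with medians of -1.41 within numbers 1 to 3 and -1.99 within numbers 4 to 6. The exact permutation test of the list mean gave p = 0.00649 (adjusted 0.0292), or an adjusted p of 0.0540 with labels permuted only within the sets.

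Of the 7 tested miRNAs of the smooth muscle growth list, 4 rose, none fell and 3 did not pass the threshold. The list had a camera adjusted p of 0.00587, lost with an estimated correlation (adjusted p = 0.166). Adjusted over the list alone, 5 rose. miR-221 and miR-222, neighbouring miRNAs that promote smooth muscle proliferation, rose by 1.73 ± 0.40 (SE) and 1.57 ± 0.41 (SE), the second call being lost without control 4, 5 or 6 or ligated 2 (limma, adjusted p up to 0.0696). miR-31 had a log2 fold change of 0.98 ± 0.30 (SE) and an adjusted p of 0.0531, or 0.0355 with the sets as a block. miR-24 had a log2 fold change of -0.06 ± 0.25 (SE). miR-21 and miR-146a also belong to this list. The median was 1.57, and the exact permutation p was 0.00216 (adjusted 0.0130). The medians were 1.61 within numbers 1 to 3 and 1.21 within numbers 4 to 6. limma's fry, which asks whether the members of a list move one way, also called these 4 lists, with adjusted p-values up to 0.00342.

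The other 14 lists did not pass in camera without the block. The endothelial-enriched list had 3 of 8 members higher, miR-221, miR-222 and miR-10b, and a median of 0.11 (adjusted p 0.303), while the exact permutation test of its mean gave an adjusted p of 0.245, or 0.0225 with labels permuted only within the sets. Its median was 0.39 within numbers 1 to 3 and -0.10 within numbers 4 to 6, and ran from -0.10 without ligated 3 to 0.32 without ligated 5. miR-126-3p and miR-126-5p, the endothelial miRNAs from the Egfl7 gene, had log2 fold changes of 0.00 ± 0.54 (SE) and -0.26 ± 0.34 (SE), and had opposite signs in the sets, with 0.40 and -0.40 for the first and 0.12 and -0.63 for the second. miR-10b rose by 0.97 ± 0.27 (SE) with an adjusted p of 0.0390, which became 0.0551 with the replicate number as a block, and was 1.42 and 0.52 within the sets. This call was lost without control 1, 3, 4 or 6 or ligated 1, 2, 3 or 6 (limma, adjusted p up to 0.0928). The shear-responsive list, fixed from miRNAs known to respond to blood flow, had miR-155, miR-21 and miR-146a higher and miR-143 and miR-145 lower among 13 members, a median of -0.19, a mean of 0.14 and a downward direction in camera (adjusted p 0.994). For change in either direction, fry gave adjusted p-values of 8.4e-09 for this list, 0.0212 for the endothelial-enriched list and 0.0732 for the contractile smooth muscle list. Among them miR-92a had a log2 fold change of -0.36 ± 0.17 (SE), miR-19a of 0.20 ± 0.20 (SE) and miR-205 of 0.59 ± 1.29 (SE), the last with 1.89 and -0.71 within the sets. The median of the shear-responsive list was 0.12 within numbers 1 to 3 and -0.40 within numbers 4 to 6. Striated muscle miRNAs had 1 of 4 members lower and a median of -1.25 (adjusted p 0.0673), and the adjusted p was 0.0123 with the replicate number as a block and 0.733 with an estimated correlation. Its median was -0.65 within numbers 1 to 3 and -1.89 within numbers 4 to 6, and miR-206, its member outside the contractile list, had a log2 fold change of -0.80 ± 0.52 (SE). The epithelial list had 1 of 7 members lower, miR-375, and its median of 1.22 and mean of 0.31 differed in sign from camera's downward direction (adjusted p 0.994). Without ligated sample 1 the epithelial median was 0.02, and it was 2.02 within numbers 1 to 3 and -0.55 within numbers 4 to 6.

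Without a block, none of the tested members passed the threshold in the red blood cell (median -0.31), neuronal (0.69), liver and kidney (-0.35), mesenchymal and fibroblast (-0.06), miR-17 family (0.18), let-7 family (-0.56), miR-99 and miR-125 clusters (-0.22), miR-23 and miR-24 clusters (-0.22), miR-15 and miR-16 family (0.25) and Dlk1-Dio3 imprinted cluster (-0.05) lists. Their camera adjusted p-values lay between 0.303 for let-7 and 0.950. The mesenchymal, miR-99 and miR-125, and Dlk1-Dio3 medians differed in sign from their mean or from camera's direction. Within numbers 1 to 3 and 4 to 6 the medians had opposite signs for the neuronal (-0.16 and 1.51), mesenchymal and fibroblast (-0.13 and 0.39) and Dlk1-Dio3 (-0.38 and 0.33) lists. Leaving out 1 sample moved the neuronal median from 0.19 without ligated 5 to 1.18 without control 2, and the mesenchymal median from -0.20 without control 2 to 0.41 without ligated 1. Other medians moved too, such as red blood cell to -0.03 without control 3, let-7 to -0.28 without ligated 1, and Dlk1-Dio3 to 0.22 without control 2. With the replicate number as a block, miR-18a of the miR-17 family had a log2 fold change of 0.80 ± 0.26 (SE) and an adjusted p of 0.0495 (0.0685 without it), and let-7i of 0.76 ± 0.51 (SE) and 0.0420 (0.442 without it). With the sets as a block, adjusted p-values were 0.00965 for miR-18a, 0.00989 for let-7i, 0.0332 for let-7f (log2 fold change -0.73), 0.0499 for let-7a (-0.79), 0.0342 for miR-15b (0.59) and 0.0304 for miR-495 of the Dlk1-Dio3 cluster (-0.70). miR-210, a hypoxia-induced miRNA, had a log2 fold change of -0.31 ± 0.31 (SE), miR-451 of red blood cells of -0.40 ± 0.62 (SE), and miR-124 of neurons of 1.22 ± 0.89 (SE). The last 2 had opposite signs in the sets, with -0.86 and 0.07 for miR-451 and -0.03 and 2.47 for miR-124.

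**Figure D2:**
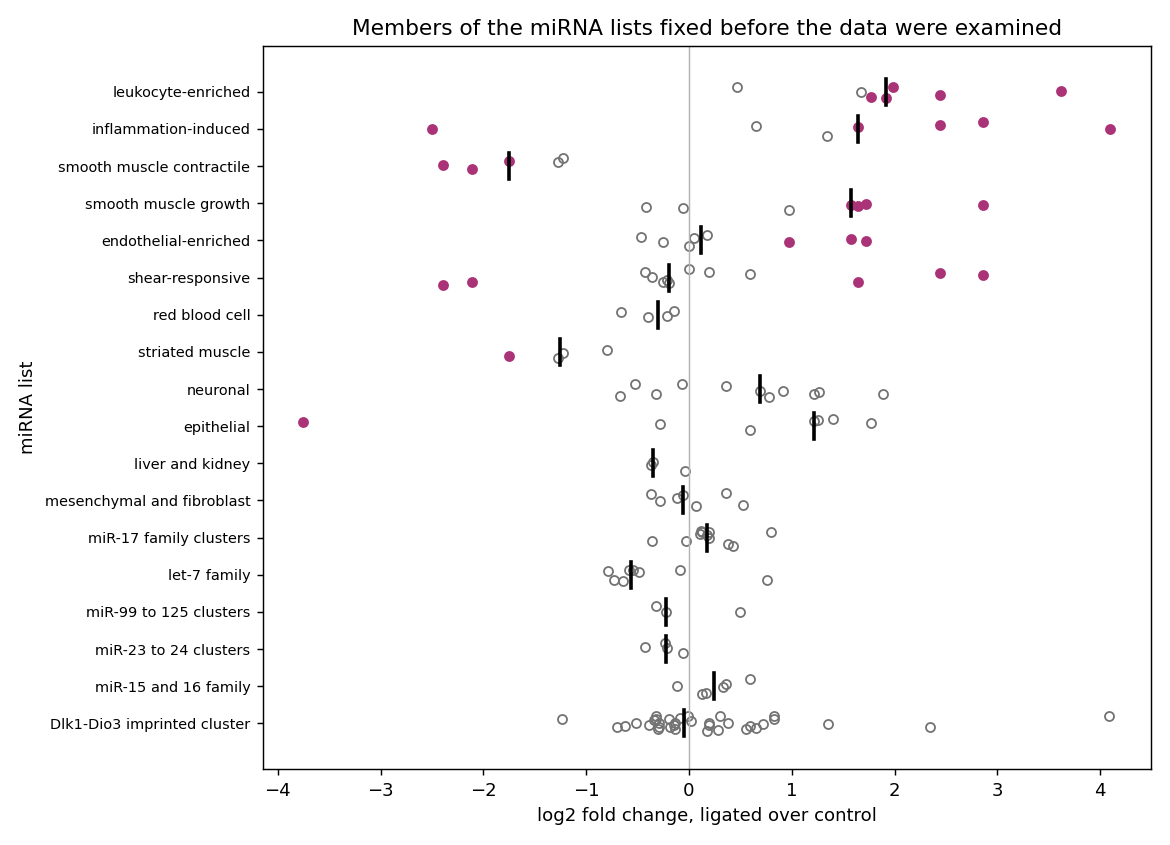
Log2 fold changes (ligated over control) of the tested members of 18 miRNA lists, 1 point per miRNA, with the median of each list as a black bar. Filled points passed an adjusted p of 0.05. Members of the leukocyte-enriched list lay between 0.46 and 3.62 and members of the contractile smooth muscle list between -2.39 and -1.23.

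Outside the lists, miR-34c, a miRNA induced by p53, rose by 2.82 ± 0.65 (SE), miR-34c* by 2.64 ± 0.67 (SE), miR-34b-3p by 2.57 ± 0.53 (SE) and miR-34a by 1.83 ± 0.53 (SE), with 1.35 and 2.31 within the sets for miR-34a. The calls of miR-34c* (without control 4, 5 or 6) and miR-34a (without control 1, 2, 3, 4 or 6 or ligated 4, 5 or 6) were lost, with limma adjusted p-values up to 0.0614 and 0.0938. Among the higher miRNAs detected in every ligated sample, those of largest size also included miR-467d at 5.27 ± 1.45 (SE), detected in 2 of 6 control samples, and miR-503 at 3.64 ± 1.03 (SE), detected in 4 of 6 control samples, with an adjusted p of 0.0425 that became 0.0714 with the replicate number as a block. The call of miR-467d held in 19 of 33 alternatives and was lost without control 1, 2, 5 or 6 or ligated 4, 5 or 6 (adjusted p up to 0.0825), and with undetected wells left missing its log2 fold change was 1.40. That of miR-503 held in 14 of 34 and was lost without control 3 or 6 or any 1 ligated sample (adjusted p up to 0.0902). miR-501-3p was detected in 0 of 6 control and 5 of 6 ligated samples, with a fitted log2 difference of 7.83 ± 1.55 (SE) and an adjusted p of 0.00908 in limma. Undetected wells of both groups were set to the detection limit there, so this is neither a measured fold nor a bound. Among the lower miRNAs, miR-375 fell by 3.75 ± 0.85 (SE), miR-378 by 2.13 ± 0.39 (SE), miR-365 by 1.85 ± 0.35 (SE), miR-107 by 1.74 ± 0.42 (SE), miR-193b by 1.32 ± 0.33 (SE) and miR-29c* by 1.19 ± 0.22 (SE). miR-378, miR-365 and miR-193b are miRNAs abundant in brown fat. Within numbers 1 to 3 and 4 to 6 the values were -1.97 (limma, adjusted p 0.442) and -5.53 (adjusted p 0.0112) for miR-375, -0.94 and -1.70 for miR-193b, and -0.94 and -1.43 for miR-29c*. The calls of miR-107 (without control 4 or 6) and miR-193b (without control 3 or 4 or ligated 5 or 6) were lost, with adjusted p-values up to 0.0526 and 0.0525. Each of these 6 was lower in the ligated sample in 6 of 6 same-numbered comparisons. The other assays of the separate run, scaled to its 4 control RNAs, showed miR-10a higher by 0.42 (exact permutation p = 0.0216, n = 6), miR-100 at -0.60 (exact p = 0.00216) and miR-99a at -0.67 (exact p = 0.00216), all two-sided, with adjusted p-values of 0.0216, 0.00288 and 0.00288. With paired numbers, an exact sign-flip test gave miR-10a p = 0.0625 and miR-100, miR-99a and miR-146b p = 0.0312 (adjusted 0.0417). On the scale of the main run, limma gave -0.41 for miR-100, -0.49 for miR-99a and 0.61 for miR-10a, with adjusted p-values of 0.275, 0.228 and 0.116. The differences within the sets were -0.57 and -0.62 for miR-100, -0.67 and -0.68 for miR-99a, and 0.30 and 0.55 for miR-10a. Scaled to snoRNA429 of that run, miR-10a had a log2 difference of 0.14 (exact permutation p = 0.351).

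The ligated samples gave lower raw Ct values, where a lower Ct means more RNA. The mean Ct of the 283 reference miRNAs was 25.5 ± 0.76 (SD, n = 6) in control and 24.5 ± 0.73 (SD, n = 6) in ligated samples, a difference of -0.99 cycles (exact permutation p = 0.0476, two-sided). This call was lost when control 3, 4, 5 or 6 or ligated 1, 2 or 3 was left out (exact p up to 0.102). The ligated sample was lower in 6 of 6 same-numbered comparisons, and an exact sign-flip test with paired numbers gave p = 0.0312, the smallest that 6 pairs allow. The difference was -0.97 within numbers 1 to 3 and -1.002 within numbers 4 to 6, where 3 against 3 samples cannot give an exact p below 0.10. Detected assays numbered 330.8 ± 8.06 (SD, n = 6) in control and 344.2 ± 9.20 (SD, n = 6) in ligated samples (exact permutation p = 0.0303), and an exact sign-flip test with paired numbers gave p = 0.0938. The unpaired call was lost without control 4, control 6 or ligated 1 (exact p up to 0.0541). The difference of 13.3 assays was 9.33 within numbers 1 to 3 and 17.3 within numbers 4 to 6. In Fisher's exact test, 0 of 117 assays with 1 to 11 detecting samples differed in detection after adjustment, and 2, miR-147 and miR-501-3p, had an unadjusted p of 0.0152.

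Among the 6 control RNAs, snoRNA135 had the largest raw difference, -1.52 cycles (exact permutation p = 0.00216, adjusted 0.0130), and Y1 the smallest, -0.08 cycles (p = 0.706 in the same exact test). U6 differed by -1.30 cycles (exact p = 0.169), snoRNA429 by -1.08 (exact p = 0.271), U87 by -0.85 (exact p = 0.0455, adjusted 0.0910) and snoRNA202 by -0.77 (exact p = 0.0325, adjusted 0.0910). The ligated sample was lower in 6 of 6 same-numbered comparisons for snoRNA135, U6, snoRNA429, U87 and snoRNA202, and in 4 of 6 for Y1. With paired numbers, an exact sign-flip test gave each of the 5 p = 0.0312 (adjusted 0.0375) and Y1 p = 0.219, and labels permuted only within the sets gave p = 0.005 (adjusted 0.006) and p = 0.585 in exact tests. After scaling, 0 of the 6 passed, with or without pairing, with snoRNA135 at 0.54 (exact p = 0.0736) and Y1 at -0.91 (exact p = 0.219). With labels permuted only within the sets, snoRNA135 and Y1 had adjusted exact p-values of 0.0300.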

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

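Tests of the 3 patterns weighed here were chosen after the results were seen, except the residual correlation of miR-193b, miR-365 and miR-378 and the counts of other splits.

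In ligated sample 1, the epithelial miRNAs miR-200b and miR-141 stood far above the other ligated arteries. miR-200b was at 3.67 against -3.79 to -1.75 in the other ligated samples, and miR-141 at -1.19 against -8.33 to -5.79. In the same sample let-7e was lower, at 3.45 against 4.57 to 5.05, let-7b was lower, at 2.18 against 3.60 to 4.43, and snoRNA135 had a raw Ct of 20.04 against 20.9 to 21.1. In control sample 2, miR-431 stood at 1.63 against -2.42 to -1.58 and miR-543 at -1.62 against -3.04 to -2.67. These 7 were found among 194 groups of values, no more than chance alone gives at about 1 in 20 if the groups are independent. They are not independent, and most of the 7 fell in ligated sample 1, in related miRNAs. The rate therefore does not settle whether that sample differs, which was not tested. Without ligated sample 1, 22 miRNAs were higher and 16 lower.

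The first pattern is the rise of leukocyte-enriched miRNAs beside lower levels of contractile smooth muscle miRNAs, of which 3 of 5 fell, although 3 of these 5, miR-1, miR-133a and miR-133b, are also 3 of the 4 tested striated muscle markers (median -1.25, miR-206 at -0.80). The difference of the list means taken inside each sample, which no reference can change, was 3.74 log2 units higher in ligated samples (exact permutation p = 0.00216, or 0.0312 with paired numbers). This argues against the choice of reference as the cause of the gap between the lists. Which miRNAs count as lower still depends on the reference, since raw Ct gave 57 higher and 0 lower. The difference of the list means was at least 3.29 within either set of numbers (exact permutation p within the sets = 0.005). Each set held 3 control and 3 ligated samples, so the split of the sets could not by itself give a difference between the groups. The lists were picked after each had separated the groups, so a gap between them was likely beforehand. Leukocyte-enriched miRNAs also rose by 1.72 more than endothelial and mesenchymal ones (exact permutation p = 0.00216, or 0.0312 with paired numbers). This cannot decide whether a smaller share of smooth muscle RNA is the whole cause, because the compared miRNAs may not be free of smooth muscle. Among them, miR-221 and miR-222 are also on the smooth muscle growth list. A smaller share of smooth muscle RNA, more leukocyte RNA in the ligated artery, and induction within its cells may all stay open. For miR-1, miR-133a and miR-133b, a different amount of striated muscle in the samples may stay open too. These explanations were not separated here.

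The second pattern is a shift of control RNAs between the sets: relative to the reference mean, snoRNA429 shifted by -1.75 and Y1 by 2.06 log2 units in samples numbered 4 to 6. U6 relative to the reference mean was lower by 1.49 log2 units in samples numbered 4 to 6 (exact permutation p = 0.00216 over samples). The sets were found in these same values, so this p is no test against chance. Moreover, 3 numbers against 3 cannot give a p below 0.10. Less RNA alone would shift every assay alike, so the sizes of these shifts argue against it. Relative to snoRNA202, the set shift of U6 was -1.89 in the main run and -0.52 in the separate run, a gap of -1.37 (exact permutation p = 0.00433, with the same limits). If the separate run used the same RNA, which is not stated, this argues against a difference between the mice as the whole cause. The raw Ct of snoRNA429 shifted between the sets by 2.98 cycles in the main run and 0.25 in the separate run, a gap that was not tested, and an effect of the main run on some assays may remain.

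The third pattern is the fall of miR-193b, miR-365 and miR-378, which are abundant in brown fat, so that fat attached to the control arteries could be a source. Over 9 other fat-associated miRNAs, the median log2 fold change was -0.284 (quartiles -0.339 and -0.124). The median and quartiles lay above the bound of -0.5 set for excluding fat, a bound written after fold changes had been seen. Of the 9, miR-193 at -1.38 and miR-26b at -0.58 lay below it, and the others ran from -0.34 to 0.41. The median was not taken as excluding fat, because these miRNAs were abundant in the ligated arteries themselves (median raw Ct 24, under 30). A small share of fat may therefore not show. This condition was added after the value was known. The mean residual correlation of the 3 miRNAs within groups and sets was 0.31, at percentile 84.4 of random trios, which leaves varying attached tissue open. The ligation itself stays open as an explanation, and was not separated here.

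Other splits of the samples bear on the counts. Among 100 splits drawn, 1, the real one, gave 25 or more calls in a direction, with 23 as the highest of the others, and 3 gave 17 or more. Counts this large were therefore unlikely by chance, but chance is not excluded. The 2 other splits with 17 or more placed 5 of the 6 samples of a set on the same side. This points to a structure of the samples. The split by the sets themselves called 71 and 87 miRNAs. The sets were found in these values, so many calls were likely beforehand. With the sets as a block the real groups gave 37 higher and 30 lower. Among the 32 splits that part every same-numbered pair, 1, the real one, gave as many higher and 1 as many lower, and the highest other count was 1. For the number of lists called by camera, 4, chance cannot be excluded: 36 of the 100 splits and 14 of the 32 gave as many, with up to 10. Exact permutation of the list means called 4 lists over all samples, and within the sets also 4, with contractile smooth muscle lost (adjusted p 0.0540) and the endothelial-enriched list gained (0.0225). With paired numbers 6 pairs cannot give a p below 0.0312, and 0 of the 18 lists passed (lowest adjusted p 0.0938).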

How the results depend on the processing

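Settings with the sets as a block, within a set, with the reference U6 and snoRNA429, with permutation within the sets, and with paired control RNAs, list means or separate-run assays were chosen after seeing the data. Over the alternatives run, no called value among 79 named miRNAs and 18 lists reversed: of 2742 values of single miRNAs 2499 kept their side of the threshold, 189 lost and 54 gained a call, and of 628 list values 614 kept it. All 42 called miRNAs kept their sign wherever they had a value, except miR-30a*, miR-30b, miR-30e* and miR-411* with raw Ct. The cause of the following moves was not tested, apart from settings with fewer samples. Raw Ct gave 57 higher and 0 lower with a median over all assays of 0.93, so all other changes are relative to that shift. The deposited value table gave 8 and 4 (median -0.22, 66.7% higher against 59.5%) and kept 10 of the 42 calls, and U6 with snoRNA429 gave 7 and 3 (median -0.26, 70% higher). The median reference, quantile normalization and assays detected in any sample moved the median to -0.14, -0.12 and -0.13. Array weights gave 51 and 50, an unequal-variance test 13 higher, and the set block 30 lower. Numbers 1 to 3 alone gave 1 and 0, and numbers 4 to 6 alone 50 and 52. Leaving out 1 sample gave 15 to 26 higher and 9 to 20 lower: 16 and 9 without control 4, 15 and 11 without control 6, and 11, 10, 11 and 11 lower without control 1, control 3, ligated 5 and ligated 6. The replicate block gave 30 higher and 22 lower, kept 36 of the 42 calls and changed no call of a result in the report other than those given beside it. An exact sign-flip of list means with the replicate block called 0 lists (adjusted p 0.0938), where 6 pairs give no p below 0.0312. An estimated correlation called 2 lists in place of 4, losing contractile smooth muscle (median -1.753) and smooth muscle growth (1.573). Within numbers 1 to 3 the contractile list lost its call (-1.418) and the endothelial list gained one (0.386). The striated muscle list gained a call with raw Ct (-0.267), the deposited table and U6 with snoRNA429 (-1.458), the replicate block (-1.253), numbers 4 to 6 (-1.91), and without control 2, 4 or 6 or ligated 1 or 3, with a range over left-out samples of -1.651 to -0.914. The number of assays detected per sample differed by 10.57 to 16.17 without 1 sample (exact p 0.00866 to 0.0541; lost without control 4, control 6 or ligated 1), by 13.33 with the replicate block (exact p = 0.0938), and by 9.333 and 17.33 within the sets. The mean raw Ct of the reference miRNAs differed by -1.187 to -0.759 without 1 sample (exact p 0.0303 to 0.102; lost without control 3, 4, 5 or 6 or ligated 1, 2 or 3), and by -0.97 and -1.002 within the sets. By scaled level, permutation within the sets called 2 of the control RNAs in place of 0. By raw Ct, the replicate block called 5 in place of 1, as did permutation within the sets. The block ended the call of miR-10a in the separate run. Averaging assays of a name was not run, since no name had more than 1 assay, nor scaling per card, nor camera with the unequal-variance test. Values near a Ct of 35 depend most on the limit.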

Other observations

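The tests in this part were chosen after the result was seen. The log2 fold changes of the arms of a hairpin, and of neighbouring miRNA genes, were more alike than in shuffled pairs. Across 81 hairpins with both arms tested, the log2 fold changes of the arms correlated with r = 0.535 (Spearman 0.5, permutation p = 1e-05, the smallest the permutations can give), across hairpins that are not independent replicates. With the 18 hairpins that had a called arm left out, r was 0.269 over 63. The arms of miR-21 (1.69 ± 0.28 and 2.86 ± 0.62, SE), miR-342 (1.99 ± 0.58 and 3.62 ± 0.86) and miR-34c (2.64 ± 0.67 and 2.82 ± 0.65) rose together, and 15 of the 18 hairpins with a called arm had arms of the same sign. Exceptions included miR-10b, whose other arm miR-10b* had a log2 fold change of -3.004 ± 2.04 (adjusted p 0.456), with undetected wells in both groups (5 of 6 control and 3 of 6 ligated samples detected). This may be a shared change of the precursor, as both arms come from it.

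Neighbouring miRNA genes, within 10000 bases in the mouse assembly GRCm38.p6, had a median difference in log2 fold change of 0.31, against 0.769 in shuffled pairs (permutation p = 1e-04, the smallest the permutations can give). A shared transcript could give this, and the 47 pairs come from 179 of 256 hairpins that matched 1 gene, many of them in the Dlk1-Dio3 cluster. Of the 34 tested members of the Dlk1-Dio3 list, 0 passed the threshold, so alike values there need not be shared changes. Among these pairs were miR-145 and miR-143 (-2.39 and -2.12), miR-34c and miR-34b (2.73 and 2.57, the first as the mean of its arms) and miR-221 and miR-222 (1.73 and 1.57). Other pairs lay far apart, such as miR-500 and miR-501 (0.80 and 5.09) and miR-503 and miR-322 (2.10 and 0.07), as means of the tested arms. miR-433, with a log2 fold change of 4.09 ± 2.08 (SE) that did not pass the threshold (adjusted p 0.284), was detected in 3 of 3 control samples numbered 1 to 3, in 0 of 3 control samples numbered 4 to 6, listed at 40, and in all 6 ligated samples. Its level differed between the groups by -0.03 within numbers 1 to 3. The fitted 8.21 within numbers 4 to 6, and the limma interaction of the sets (adjusted p 0.000362), come from the value given to those 3 undetected wells and measure no size of change.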
